A study of Homo sapiens with 67 samples.

How the data were processed

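Peripheral blood mononuclear cells were prepared from blood, and total RNA was isolated on silica columns, per the labels' protocols. Single-stranded cDNA was fragmented and biotin labelled with an Affymetrix whole-transcript terminal labelling kit and hybridised to 67 arrays, 35 from IBS samples and 32 from healthy control samples, per the labels. The authors processed the arrays with Affymetrix Expression Console, per the submitters' processing notes. The background correction, the normalization, the summarization algorithm, the software version and the genome build are not given in the sources used here. The deposited table holds 1 column per sample and 1 row for each of 70523 probe sets. Its values are taken as log2 expression from their range of 0.80 to 14.8, and the column medians, 5.88 ± 0.04 (SD, n = 67), are close together, as after a normalization between arrays by the authors. Scanner files were not used here.

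Probe sets were named from GEO's platform annotation. It lists 25324 of the probe sets, 23781 with 1 gene symbol and 1543 with several, and leaves 45199 unlisted. A probe set with several symbols was not used, and an unlisted one is unnamed here, not without a gene. Symbols were updated through the RefSeq gene table of the assembly GRCh38.p14, which was used only for names and chromosomes; 303 symbols changed and 4 were not found in it. No coordinates are given because the build of the array annotation is not stated. Probe sets of Y-linked genes and of XIST with its antisense gene, 360 in all, were left out of every test. The probe set with the highest mean over all samples stood for each of the 504 genes with several, which left 22347 genes. Genes were tested where the mean over all 67 samples exceeded 4.93 log2 units, the 30th percentile of all probe sets, which kept 18487.

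Arrays give no read depth, so signal over background sets what can be measured. The 23 background probe sets, which match no human sequence, had means from 1.61 log2 units at 3 GC bases to 12.1 at 25, and from 2.93 to 5.03 between 12 and 15 GC bases. Background therefore depends on probe composition, and a dim gene cannot be told from background by its level alone. The mean of the background probe sets with 11 to 15 GC bases was 3.61 ± 0.19 (SD, n = 35) in IBS and 3.67 ± 0.30 (SD, n = 32) in healthy controls. The interquartile range of the relative log expression, each gene's deviation from its median over all arrays, was 0.17 ± 0.06 (SD) in IBS and 0.20 ± 0.08 (SD) in healthy controls. No label gives a batch, date, age or IBS subtype, so none of these could be tested, and a difference between the groups in them is not accounted for. Sex is not in the labels either and was covered only through a score of sex-linked genes as a covariate.

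Groups and replicate numbers were taken from the sample titles. The test for single genes was limma (lmFit and eBayes, defaults, two-sided) with disease status as the only term, adjusted by Benjamini-Hochberg over all genes tested. Gene lists, 40 in number, were fixed with the tests and most alternatives before the data were examined. The list score was the mean log2 value of the tested members in each sample, and the difference of group means was tested by a two-sided permutation test with 100000 resamples, adjusted by Benjamini-Hochberg over the lists. A list needed 5 tested members. Mast cell and basophil markers had 4 and mitochondrially encoded genes 0, so 38 lists were tested. Limma camera, with a preset and with an estimated correlation, and fry were run beside the permutation test. Camera compares a list with all other genes, and fry asks whether its members move one way on balance. Scores on the first 10 principal components of the centred values were compared by the same permutation test. Intervals are 95% t intervals of the difference.

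The genes named are, in each direction, the 10 with the smallest p, since none passed the threshold, the 3 tested members with the smallest p of each list described, and FKBP5, NR3C1, TNF, IL6, IL10, IL1B, CXCL8, TLR4, SLC6A4 and TNFSF15. Genes at the ends of a principal component are named by their loading. A rule fixed before the data were examined set the first 3 groups, and the names along the components were chosen after their loadings were seen.

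The gene test was tested on simulated data, made from the residuals of the real arrays under shuffled group labels, in 20 draws with 200 planted genes each, 50 for each of 4 sizes. The list test was tested in 20 draws with a planted shift. With no shift, 5.70% of lists had a permutation p under 0.05. Alternatives covered the filter on dim genes, quantile normalization, median centring, the variance model, array weights, the replicate number as a block, residual principal components, cell type scores, a sex-linked score and array quality as covariates, the Wilcoxon rank sum test, the mean over probe sets of a gene, the list statistic, and leaving out each sample in turn. Random splits of the 67 samples into groups of the same sizes, 100 with the real split, were fitted in the same way. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.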

Results

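Irritable bowel syndrome (IBS) is a disorder of recurrent abdominal pain with altered bowel habit. The study asked whether gene expression in blood differs between IBS and health. It profiled peripheral blood mononuclear cells (PBMC), the lymphocytes and monocytes that remain after granulocytes and most red cells are removed from blood. Total RNA of 35 samples with IBS and of 32 from healthy controls was hybridised to whole-transcript Affymetrix arrays, with 1 array per sample. All values below are deposited log2 expression values and means of 35 IBS against 32 healthy control samples, unless another n is given. The labels name separate samples but do not say that each came from a different donor, so p-values measure the spread between these samples, part of which may be technical. The number of arrays limits the precision. The array medians averaged 5.88 ± 0.04 log2 units (SD, n = 67), and the 2211 pairs of samples correlated between 0.954 and 0.993, with no pair identical.

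No gene passed the test between IBS and healthy control, and the genes with the smallest p differed by small amounts. Among those with a higher mean in IBS, USP32P2, a pseudogene on chromosome 17, was at 6.76 ± 0.16 (SD, n = 35) in IBS and 6.63 ± 0.15 (SD, n = 32) in healthy controls, a log2 difference of 0.13 (limma p = 8.77e-04). NAAA, the lysosomal amidase that breaks down palmitoylethanolamide, was at 7.80 ± 0.30 (SD) in IBS and 7.60 ± 0.27 (SD) in healthy controls, a log2 difference of 0.20 with a standard error of 0.067 (p = 0.00502). RNF135, a ubiquitin ligase that acts on the viral RNA sensor RIG-I, differed by 0.07 (p = 0.00397), and MTX1, a protein import component of the outer mitochondrial membrane, by 0.06 (p = 0.00271). SMCR8, an autophagy regulator that binds C9orf72, differed by 0.08, and NUAK2, a kinase related to AMPK, by 0.13. The other genes of this set were FAM106C at 0.34, USP32P1 at 0.13, MIR619 at 0.09 and FAM238B at 0.06. USP32P1, USP32P2 and FAM106C belong to families of near-identical copies, so the probes could read more than 1 copy and these values are uncertain.

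Among the genes with a lower mean in IBS, MFAP1, a spliceosome component, had the smallest p, with a log2 difference of -0.10 and a standard error of 0.029 (limma p = 0.00115). BRD7, a bromodomain subunit of a SWI/SNF chromatin remodelling complex, differed by -0.14 (p = 0.0106), and RRS1, a ribosome assembly factor, by -0.09 (p = 0.00899). METTL18, a histidine methyltransferase, differed by -0.09, PHLDB2 by -0.08 and the centrosomal protein gene CEP19 by -0.10. RNA5SP110, a pseudogene of 5S ribosomal RNA, differed by -0.18, FAM74A4 by -0.15, MIR320E by -0.07 and the ankyrin repeat pseudogene ANKRD20A3P by -0.20. The last 4 are also members of multicopy families and are uncertain for the same reason. All 20 genes had an adjusted p of 0.9999, so none is a call.

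Of the 18487 genes tested with limma, 0 passed an adjusted p of 0.05 and 290 had an unadjusted p under 0.05, which is 1.57% of the genes. The Wilcoxon rank sum test also called 0 genes, with 288 at an unadjusted p under 0.05. Of the 290 genes, 207 had a higher and 83 a lower mean in IBS. After each array was centred on its median, 132 were higher and 157 lower of 289 such genes. After a further quantile normalization, 171 were higher and 120 lower of 291. The 95% interval of the difference lay within 1.2-fold either way for 17933 genes, 97% of those tested, and within 1.5-fold for 18473. The largest absolute difference of any gene was 0.35 log2 units. In simulated data of the same samples, limma recovered 27.6% of the genes planted at a fold of 1.07, 79.5% at 1.15 and 94.9% at 1.23. These shares hold for 200 genes planted together, larger differences among them. Fewer real differences would face a stricter adjusted threshold, and their recovery was not measured. When 3 principal components of the residuals were added as covariates, 49 genes were called, 45 of them higher in IBS, and a median of 349 genes was called the same way in random splits of the samples.

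Genes often studied in IBS and in stress biology did not pass the test either. FKBP5, a cortisol-induced chaperone of the glucocorticoid receptor, differed by -0.08 ± 0.063 (SE), and NR3C1, the receptor itself, by -0.016 ± 0.031 (SE). The proinflammatory cytokine genes TNF and IL6 differed by 0.07 ± 0.070 and 0.0070 ± 0.034 (SE), and IL10, an anti-inflammatory cytokine gene, by -0.0035 ± 0.036 (SE). IL1B and CXCL8, which activated monocytes release, differed by 0.17 ± 0.20 and 0.24 ± 0.21 (SE), with wide SDs of 0.81 and 0.87 within the IBS group and 0.91 for both within the healthy controls. TLR4, the receptor for bacterial lipopolysaccharide, differed by 0.11 ± 0.094 (SE), and by -0.032 with cell composition covariates. SLC6A4, the serotonin transporter, differed by -0.020 ± 0.029 (SE) and TNFSF15, a cytokine gene linked to bowel disease, by -0.039 ± 0.036 (SE). TNFSF15 had a mean of 4.964 in IBS and 5.003 in healthy controls, close to the filter on dim genes. IL10, at 5.184 and 5.188, and IL6, at 5.515 and 5.508, were low as well. SLC6A4, at 6.132 and 6.152, was near the mean of 6.157 of the background probe sets with 17 GC bases. The GC content of its probes was not examined. The remaining genes named here had higher means, which alone do not show signal over background. A dim gene cannot be told from background by its level alone, so small SEs do not show that TNFSF15, IL10, IL6 and SLC6A4 are unchanged. The unadjusted limma p of these 10 genes lay between 0.197 for FKBP5 and 0.922 for IL10.

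Gene lists fixed before the data were examined were then compared as the mean of their members in each sample. None of the 38 lists passed the permutation test, at an adjusted or an unadjusted p of 0.05. Classical monocyte markers had the smallest p. Their mean was 8.55 ± 0.41 (SD, n = 35) in IBS and 8.39 ± 0.47 (SD, n = 32) in healthy controls, a fold of 1.12 and a log2 difference of 0.17 with a 95% interval of -0.05 to 0.38 (permutation p = 0.130, adjusted p = 0.975). All 15 members had a higher mean in IBS, and 0 were called over all genes or adjusted over the list alone. S100A12, a calcium-binding alarmin of myeloid cells, differed by 0.32 (limma p = 0.0303), and its relatives S100A8 and S100A9, the subunits of calprotectin, by 0.16 and 0.18. Limma camera with a preset correlation called this list (adjusted p = 1.17e-07), and the call was lost with adjusted p = 0.933 with an estimated correlation. The difference turned to -0.025 when the 17 arrays with the widest relative log expression, 8 of them IBS, were left out, a setting chosen after the data were seen.

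**Figure D1:**
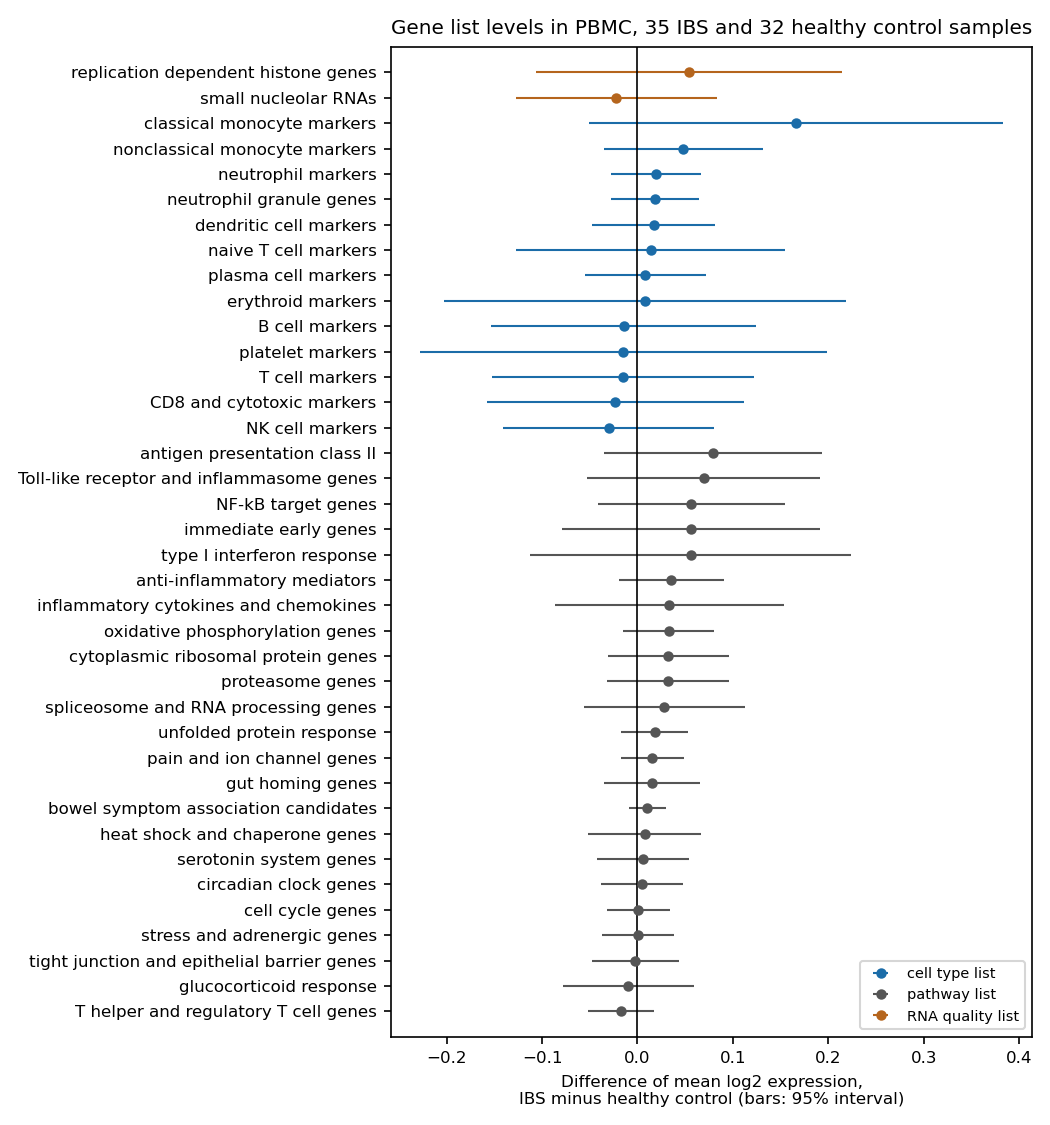
Differences of list means in log2 units on the horizontal axis, IBS minus healthy control, for the 38 gene lists on the vertical axis; points are differences between 35 IBS and 32 healthy control samples and bars are 95% intervals. Every interval spans 0, and classical monocyte markers lie farthest from it at 0.17.

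Markers of the other cells of a PBMC preparation differed by less. NK cell markers had the lowest difference, -0.030 ± 0.055 (SE), with 11 of 15 members lower in mean, among them the NK receptor genes KLRC1 at -0.18 and KLRD1 at -0.13 and the transcription factor gene TBX21 at -0.07. T cell markers differed by -0.015 ± 0.069 (SE), with CD247 and CD3D, both of the T cell receptor complex, at -0.05 and -0.06, and the signalling regulator UBASH3A at 0.09. CD8 and cytotoxic markers differed by -0.023 ± 0.067 (SE), with granzyme B (GZMB) at -0.09, FGFBP2 at -0.09 and GZMM at 0.022. B cell markers differed by -0.014 ± 0.069 (SE), with BANK1 at -0.07, CD72 at -0.05 and CD79A at -0.03. Naive T cell markers differed by 0.014 ± 0.071 (SE), with FHIT at 0.10, LRRN3 at -0.10 and PCSK5 at 0.03. Nonclassical monocyte markers differed by 0.048 ± 0.042 (SE), with TCF7L2 at 0.14, LILRB1 at 0.08 and LYPD2 at 0.06. Dendritic cell markers differed by 0.017 ± 0.032 (SE), with CD1C and CLEC10A at 0.10 and LILRA4 at 0.04. Plasma cell markers differed by 0.0083 ± 0.032 (SE), with CD38 at 0.04, TXNDC5 at 0.05 and MZB1 at 0.017. CD38 turned to -0.030 with array weights and to -0.0043 with 1 sample left out. The permutation p of these 8 lists lay between 0.259 and 0.847, and 0 of their members were called adjusted over the list alone.

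Markers of neutrophils, platelets and red cells were compared in the same way. Neutrophil markers differed by 0.019 ± 0.024 (SE) and neutrophil granule genes by 0.018 ± 0.023 (SE). CSF3R, the receptor for granulocyte colony-stimulating factor, which monocytes also carry, was at 0.15, CXCR2 at -0.024 and MMP25 at 0.025. The granule genes CEACAM6, AZU1 and BPI were at 0.06, 0.04 and 0.04. Platelet markers differed by -0.015 ± 0.11 (SE), with ITGA2B at -0.08, MYL9 at -0.08 and GP6 at -0.05. Erythroid markers differed by 0.0078 ± 0.11 (SE), with XK at -0.03, HBM at 0.025 and SELENBP1 at 0.020. The permutation p of these 4 lists lay between 0.416 and 0.943, and 0 members were called over all genes or adjusted over the list alone.

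The innate immune lists had higher means in IBS without passing the permutation test. Antigen presentation class II genes differed by 0.08 ± 0.057 (SE, permutation p = 0.170), with 11 of 13 members higher in mean, among them HLA-DMA, which loads peptides onto class II molecules, at 0.11, the lysosomal reductase IFI30 at 0.18 and the protease CTSS at 0.17. Toll-like receptor and inflammasome genes differed by 0.07 ± 0.061 (SE, p = 0.260), with 16 of 18 members higher, including the adaptor MYD88 at 0.09, the receptor NOD2 at 0.08 and CD14 at 0.18. CD14 is also a member of the monocyte list. The difference of the Toll-like receptor list was 0.0058 with array weights. It turned to -0.024 ± 0.019 (SE) with cell composition covariates, a fit whose list score leaves out CD14 as a monocyte marker. It turned to -0.017 without the 17 arrays named above. Without those arrays CD14, CTSS and IFI30 turned to -0.012, -0.045 and -0.024. NF-kB target genes differed by 0.06 ± 0.049 (SE, p = 0.259), with 13 of 16 higher, among them the NF-kB inhibitor NFKBIA at 0.22 (limma p = 0.0395), IRF1 at 0.12 (limma p = 0.0128) and TNFAIP2 at 0.13. Immediate early genes, which many stimuli and the handling of blood switch on within minutes, differed by 0.06 ± 0.068 (SE, p = 0.413), with FOS at 0.19, ZFP36 at 0.17 and JUNB at 0.14. Camera with a preset correlation called these 4 lists (adjusted p = 0.0132, 0.0211, 0.0211 and 0.0180), each lost at adjusted p = 0.933 with an estimated correlation, and the directional test of fry called none (adjusted p = 0.932 for each).

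Inflammatory cytokines and chemokines differed by 0.034 ± 0.060 (SE, permutation p = 0.583), with the chemokine CCL4 at -0.17 (limma p = 0.0323), IL18 at 0.09 and CXCL8 at 0.24. Anti-inflammatory mediators differed by 0.036 ± 0.028 (SE, p = 0.202), with the haem-degrading enzyme HMOX1 at 0.09, IL10RB at 0.07 and TGFB1 at 0.07. The type I interferon response differed by 0.06 ± 0.084 (SE, p = 0.538), with 21 of 22 members higher in mean, including IFI6 at 0.15, IFIT3 at 0.08 and OAS1 at 0.06. That difference was 0.0010 with 1 IBS sample left out. T helper and regulatory T cell genes differed by -0.017 ± 0.017 (SE, p = 0.320), with IL17A, the signature cytokine gene of Th17 cells, at -0.11 (limma p = 0.0114), TBX21 at -0.07 and STAT6 at 0.04. IL17A had a mean of 4.92 in IBS and 5.03 in healthy controls, close to the filter of 4.93 on dim genes. Gut homing genes differed by 0.015 ± 0.025 (SE, p = 0.547), with CCR2 at 0.14, the integrin genes ITGB7 at 0.03 and ITGAE at -0.014. CCR2 turned to -0.016 with array weights, -0.013 with cell composition covariates and -0.024 without the 17 arrays of widest relative log expression. In these 5 lists 0 members were called over all genes or adjusted over the list alone.

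**Figure D2:**
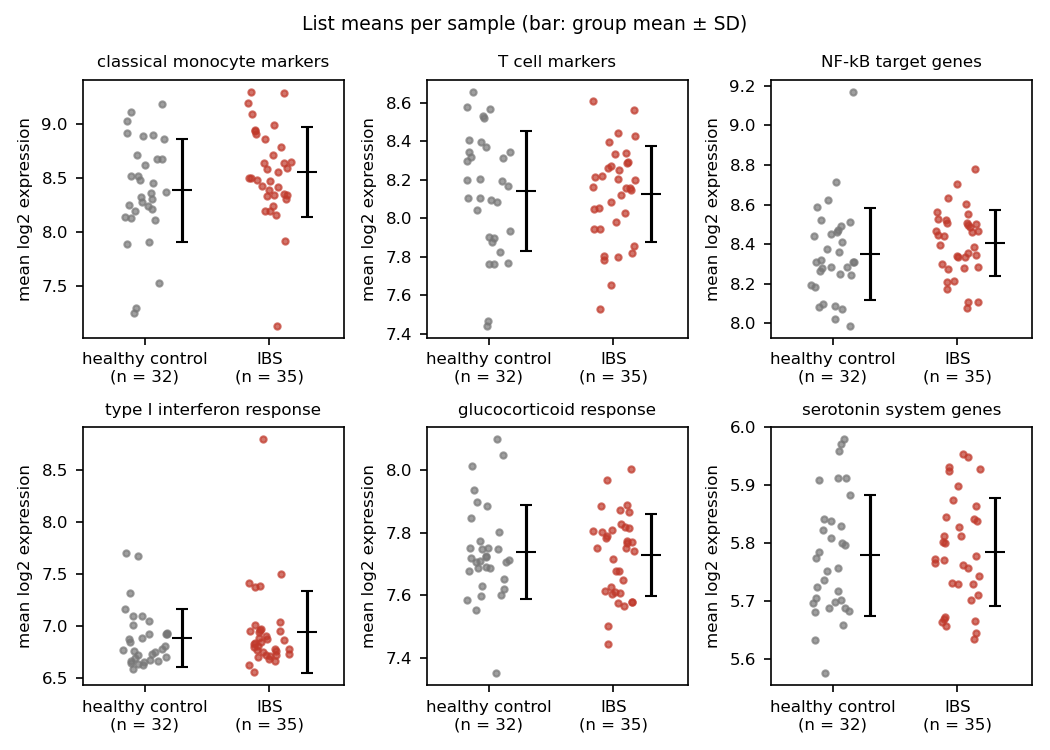
Mean log2 expression of 6 gene lists on the vertical axes for 32 healthy control samples (grey) and 35 IBS samples (red); each point is a sample, and bars are the group mean ± SD. The groups overlap in every panel, and the SDs of the interferon list are 0.40 in IBS, or 0.23 with 1 sample left out, and 0.28 in healthy controls.

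Lists tied to hypotheses about IBS had narrow intervals around 0 for the members tested. These ran from 11 of 22 pain and ion channel genes to 17 of 18 glucocorticoid response genes. The serotonin list had the lowest level of these 6 lists, 5.785 in IBS and 5.779 in healthy controls, and its member HTR3E was at 5.15 in IBS. The tight junction, stress, pain and bowel symptom lists averaged 6.462, 6.624, 6.680 and 6.750 in IBS. Background probe sets averaged 6.157 at 17 GC bases and 7.111 at 19. A dim gene cannot be told from background by its level alone, so a narrow interval does not show that genes at such levels are unchanged. The glucocorticoid response list differed by -0.0096 (95% interval -0.08 to 0.06, permutation p = 0.783), with FKBP5 at -0.08, DDIT4 at -0.11 and the phosphatase DUSP1 at 0.14. Stress and adrenergic genes differed by 0.00062 (interval -0.04 to 0.04, p = 0.975) and lay on the other side of 0 after quantile normalization or median centring of the arrays, with ADRA2A at -0.04, CRHBP at 0.04 and GNB3 at 0.020. Serotonin system genes differed by 0.0059 (interval -0.04 to 0.05, p = 0.808), with SLC6A4 at -0.020, HTR1A at 0.03 and HTR3E at -0.022. Pain and ion channel genes differed by 0.016 (interval -0.018 to 0.05, p = 0.356), with the opioid-related receptor gene OPRL1 at 0.03, P2RX4 at 0.05 and P2RX7 at 0.06. Tight junction and epithelial barrier genes, mostly expressed outside blood, differed by -0.0021 (interval -0.05 to 0.04, p = 0.927), with CDH1 at -0.04, CLDN7 at -0.03 and CLDN15 at 0.012. Bowel symptom association candidates differed by 0.010 (interval -0.0093 to 0.03, p = 0.309), with BAG6 at 0.04, PHF2 at 0.025 and CDH1 at -0.04. In these 6 lists 0 members were called over all genes or adjusted over the list alone.

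Housekeeping lists differed by small amounts as well. Oxidative phosphorylation genes differed by 0.033 ± 0.024 (SE, permutation p = 0.173), with the cytochrome c oxidase subunit genes COX7B at 0.12 (limma p = 0.0146), COX5B at 0.05 and COX6C at 0.027. Proteasome genes differed by 0.032 ± 0.032 (SE, p = 0.316), with the immunoproteasome subunit genes PSMB10 at 0.06 (limma p = 0.0385) and PSMB8 at 0.06, and PSMB1 at 0.06. Cytoplasmic ribosomal protein genes differed by 0.032 ± 0.032 (SE, p = 0.309), with RPL11 and RPS15A at 0.07 and RPS21 at 0.06. Camera with a preset correlation called these 3 lists (adjusted p = 0.0132, 0.00718 and 0.0132), and all 3 calls were lost at adjusted p = 0.933 with an estimated correlation. Spliceosome genes differed by 0.028 ± 0.042 (SE, p = 0.509), with SRSF5 and U2AF1 at 0.06 and U2AF2 at 0.027. The unfolded protein response list differed by 0.018 ± 0.018 (SE, p = 0.314), with ATF4 at 0.06, HSPA5 at 0.07 and PDIA4 at 0.03, and heat shock genes by 0.0074 ± 0.030 (SE, p = 0.804), with DNAJA1 at 0.08, HSPA6 at 0.05 and HSPE1 at -0.04. Circadian clock genes differed by 0.0043 ± 0.022 (SE, p = 0.844), with BMAL1 at 0.03, DBP at 0.022 and NPAS2 at -0.018. Cell cycle genes differed by 0.00063 ± 0.017 (SE, p = 0.969), with AURKB at 0.03, CENPF at -0.03 and MCM4 at -0.025. The cell cycle, heat shock and circadian lists changed sign under quantile normalization or median centring.

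The lists for RNA quality did not separate the groups. Small nucleolar RNAs differed by -0.022 ± 0.053 (SE, permutation p = 0.675), with SNORD13 at 0.04, SNORD3A at 0.04 and SNORD60 at -0.05. Replication dependent histone genes, whose messages mostly lack a poly(A) tail, differed by 0.05 ± 0.080 (SE, p = 0.505), with H2BC21 and H2BC12 at 0.09 and 0.08 and H1-4 at 0.08. Over all lists, 37 of 38 intervals lay inside 1.2-fold and all 38 inside 1.5-fold. Of the 520 distinct list genes, 7 had an unadjusted limma p under 0.05, and 0 were called over all genes or adjusted over the list alone. In simulated data, a shift of a whole list by a fold of 1.07 gave an unadjusted p under 0.05 in 65.7% of lists, and a fold of 1.15 in 89.7%. These shares average over lists of unlike precision, before adjustment. The SE of the difference ran from 0.0097 for bowel symptom candidates to 0.11 for classical monocyte markers, so a shift is harder to see in the latter.

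The main axes of variation between the samples were then compared between the groups. The first principal component held 37.7% of the variance of the tested genes. At one end lay small nucleolar RNAs such as SNORA11, SNORA80E and SNORD17 with pseudogenes of 5S ribosomal RNA. At the other end lay FGL2, PPBP, IL7R, IFI44L and CYBB, genes of monocytes, platelets, T cells and interferon signalling, with the microRNA genes MIR4295, MIR548W and MIR548X. Small RNA genes made up all 25 genes listed at the first end and 5 of 25 at the other. The second component, with 11.3%, set EGR1, CXCL8, IL1B, PTGS2, VCAN and S100A12, myeloid and early response genes, against the T cell genes IL7R, LEF1, LRRN3 and TRAT1. None of the first 10 components differed between IBS and healthy control in the permutation test (lowest p = 0.121, lowest adjusted p = 0.532). The first component differed by -0.07 ± 0.25 (SE) of its SD and the second by 0.28 ± 0.24 (SE).

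**Figure D3:**
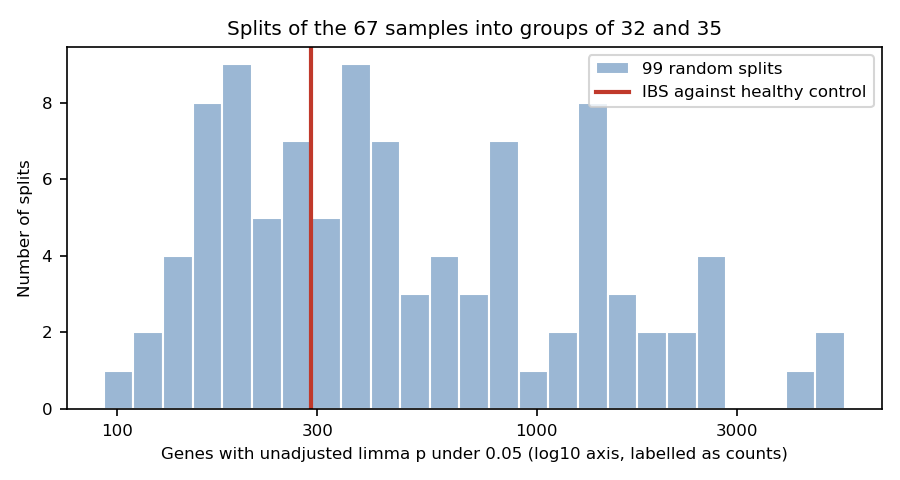
Number of genes with an unadjusted limma p under 0.05 on the horizontal axis, on a log10 scale, in 99 random splits of the 67 samples into groups of 32 and 35 (bars, number of splits on the vertical axis) and in the split into IBS and healthy control (red line). The real count of 290 lies within the random counts, which run from 93 to 5430 with a median of 402.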

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

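The alternatives chosen after the data were seen were leaving out the 17 arrays with the widest relative log expression, the unnamed probe sets, 10 residual components, the first 3 components of expression and the background probe level as covariates. The limma count of 0 genes past adjusted p 0.05 was also 0 under every alternative run except those with residual principal components as covariates, where it was 49 with 3 components and 1053 with 10; residual components leave the group difference as it is and shrink its error, and the splits described further on, fitted with 3 components only, call more genes in the same way. At an unadjusted p under 0.05 the count ran from 231 to 465 with each sample left out in turn, and was 394 with no filter, 231 with the stricter filter, 287 with trend and robust eBayes, 2016 with array weights, 631 with cell type scores, 1142 with the first 3 components, 1358 with the background level and 301 without the 17 widest arrays. Among the 28130 unnamed probe sets 0 were called and 707 had an unadjusted p under 0.05. The count of 0 lists was 4 with 3 residual components (classical monocyte markers, Toll-like receptor, anti-inflammatory and neutrophil granule lists) and 8 with camera at a preset correlation, and 0 under every other alternative run, each of the 67 samples left out included. No component differed without the filter, with genes scaled to SD 1 or after a further quantile normalization, the 3 alternatives run for components. Without 1 IBS sample the monocyte list had an unadjusted p of 0.0426 (difference 0.21, adjusted p = 0.897), and its difference ran from 0.13 to 0.21 over the samples left out, was 0.03 with array weights and 0.12 with the background level as a covariate. Of the 38 lists 23 changed sign under at least 1 alternative, 11 of them without the 17 widest arrays. Of the 139 named genes 25 did, TLR4, CD14, CTSS, IFI30, CD1C, TGFB1, IL10RB and CCR2 among them without those arrays. The 20 with the smallest p did not, which says little, since they were picked from the main fit for a large difference relative to its error. The mean and the median member differed in sign for 2 lists, cell cycle and tight junction genes, and the direction by camera, which is relative to the other genes, differed from the mean for 6. The labels do not say whether replicate numbers shared by both groups pair the samples. Over 32 numbers the correlation of deviations averaged 0.068 within a number and -0.002 between other numbers. Of these pairs 15 were over 0.1, and 1 sample correlated best with its own number. Matched persons need not correlate in expression, so these values cannot exclude a matched design. With the replicate block 0 genes were called and 507 had an unadjusted p under 0.05, and 0 lists were called. The cause of the other changes was not tested. Background probes limit what can be said of dim genes, as their level depends on probe composition.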

Other observations

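Written after their result was seen were the count of splits for the gene comparison, the use of the planned permutation test to weigh the camera call, and the comparison of spread. The fit with the first 3 components of expression and the shift planted in the genes called with residual components were added after the data were seen but before their own result, and the other tests were set before their result was seen.

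Samples from healthy controls were more spread than IBS samples for 14453 of 18487 genes, and the reverse held for 4034. The median log2 ratio of variances, IBS over healthy control, was -0.39, with a bootstrap 95% interval of -0.79 to 0.06 (permutation p = 0.0989, 1000 permutations), and -0.11 without the 17 arrays of widest relative log expression. Array measures had the same direction. The SD of the background level at 11 to 15 GC bases was 0.19 in IBS and 0.30 in healthy controls. That of the relative log expression range was 0.06 and 0.08. The first principal component followed this background level (Pearson r = 0.92). Whether array background accounts for the wider spread was not tested. Gut homing genes, which direct lymphocytes to the intestine, had an SD of 0.08 in IBS and 0.12 in healthy controls (permutation p = 0.0047, adjusted p = 0.178 over 38 lists), and replication dependent histone genes had SDs of 0.28 and 0.37. The type I interferon list had an SD of 0.40 in IBS and 0.28 in healthy controls (p = 0.776), but 0.23 in IBS with 1 sample left out, so its direction rests on that sample. None of the 38 lists passed the adjusted test of spread, and 2 had an unadjusted p under 0.05.

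The real split into IBS and healthy control called 0 genes, a count that any split reaches, so that 100 of 100 splits called at least as many by construction and the count tests nothing. The highest of the other splits called 150 genes, and 3 of 99 random splits called any. At an unadjusted p under 0.05, 64 of 100 splits gave 290 genes or more and the highest gave 5430 against a random median of 402. Some splits thus give many times the real count, as many genes vary together over these samples; what drives that structure was not tested by these splits.

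With 3 residual principal components as covariates, 49 genes were called, 45 higher in IBS, among them the myeloid genes CTSB, PILRA, CD68, FCN1 and S100A12. The 4 lower genes were CALCB at -0.06 and the 5S ribosomal RNA pseudogenes RNA5SP460 at -0.27, RNA5SP229 at -0.23 and RNA5SP110 at -0.18. Whether myeloid genes are more common among the 49 than elsewhere was not tested. Of 100 splits fitted with 3 residual components 64 called as many or more, the highest 9243, so chance cannot be excluded. With the first 3 components of expression as covariates 0 of the 49 were called and their median difference fell from 0.12 ± 0.025 (median SE) to 0.04 ± 0.025, so the calls may come from variation along the disease axis that covariates taken from residuals cannot remove. In that fit 48 of the 49 kept their direction and 17 had an unadjusted limma p under 0.05, but the 49 were picked from these same samples. That fit called at most 1 gene in any random split. It called between 10 and 38 of the 49, with a median of 26, once a shift of 0.12 was planted in each of them in random splits. This shift, the median difference of the 49, was the same for every gene, while their real differences were unequal. A true difference along these components would be removed as well. A difference in monocyte share stays open. With cell type scores as covariates, the median difference of the 43 higher genes outside the cell lists was 0.04 against 0.10 before. The adjusted value was 35.5% of the earlier one, and its median standard error was 0.03. In a separate fit without the 17 arrays of widest relative log expression and without cell type scores, the median difference was 0.021. That separate fit does not test monocyte share.

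Camera with a preset correlation called classical monocyte markers, which include abundant transcripts such as S100A9 at 10.4 in IBS and 10.2 in healthy controls. Correlation between the genes of the list is a candidate explanation of that call, since the permutation test, which keeps the sample as the unit, gave p = 0.130 and the estimated correlation was 0.781. A larger monocyte share with a smaller lymphocyte share could not be told apart from no change: the monocyte score minus the mean of the T, B and NK cell scores differed by 0.19, with a 95% interval of -0.05 to 0.43 (permutation p = 0.127). The interval reaches past the difference of the monocyte list itself, 0.17. The score contains that list, and its own difference already exceeded 0.17, so this comparison says nothing for or against the explanation, which stays undecided. Cell counts were not used here.

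The first principal component rose with the mean of the background probes with 11 to 15 GC bases, with Pearson r = 0.92 and Spearman rho = 0.882 over 67 arrays (permutation p = 1e-05 for each, the smallest that the permutations can give; adjusted p = 1.5e-05 over 3 relations; r = 0.891 without the 2 arrays farthest from the median). It was 0.878 within IBS and 0.945 within healthy controls, so labelling, hybridisation or scanner background may set much of this axis. Different recovery of small RNAs between the preparations stays open too, although 5 of the 25 genes listed at the opposite end are microRNA genes: the component computed without the 1326 small RNA genes had r = 0.73 and rho = 0.667 with their mean (p = 1e-05, adjusted p = 1.5e-05 for each; r = 0.649 without the 2 farthest arrays; 0.663 within IBS and 0.774 within healthy controls). A balance of T cells against monocytes is argued against as the source of this axis, with r = 0.13 and rho = 0.103. The permutation p was 0.309 and 0.405, adjusted p the same. The upper 95% bound of r was 0.355, and r was 0.0967 without the 2 farthest arrays. A score of T cells minus monocytes cannot show a change of both in one direction, and FGL2, CYBB and IL7R lay at the same end. The difference of the component between IBS and healthy control did not pass the permutation test (p = 0.781), and no other biological explanation was tested.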
